A study of Mus musculus with 6 samples.

How the data were processed

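RNA was taken from the tibialis anterior muscle of 3 mice without Prmt7 and 3 wild-type mice, all C57BL/6 and 8 months old, per the labels. Total RNA was extracted with Trizol from frozen muscle and made into Illumina libraries, per the labels' protocols. The genome build was mm10 per the submitters' processing notes, and coordinates are given in it, counted from 1. The aligner, the counting program and the annotation are not given in the sources used here.

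The authors deposited 1 table of genes, with a mean signal per genotype (normalized read count), a log2 ratio, a p-value and an FDR, and 2 tables exported from the Ingenuity pathway program. The comparison was made by the authors with DESeq, per the name of the deposited table, in a version not given in the sources used here. The log2 column equals the log2 ratio of the 2 deposited means to within 1.3e-14 for genes above 0 in both. The deposited FDR differed from a Benjamini-Hochberg adjustment of the deposited p-value over the 14617 listed genes by at most 0.000136, and both called 396 genes. The filter that set which genes are listed is not given in the sources used here; the lowest mean over both groups was 3.55. The deposited table marks 31 genes as 200 bases or shorter, and these were kept. The pathway tables give an activation score, a p-value of overlap and the share of molecules, which the authors made from genes past an absolute log ratio of 0.95, per the file headers. 1 line of the gene table was not analysed here.

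No column header names a genotype. The first column of means was read as WT and the second as KO from the order of the 2 words in the table's name. The direction of every comparison depends on this reading.

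A mean of counts divided by a factor per library is a sum of whole multiples of 1 step per library. The steps were searched for in the 300 lowest values of each column, and every value was then solved for whole multiples, with a tolerance of 1e-13 of the value. One step explained 4.67% of the low values in WT and 5% in KO, while 2 steps explained 100% in both. For all 14617 genes there was exactly 1 solution per column, so the means are those of 2 libraries per genotype. The labels name 3 mice per genotype; which 2 entered the means is not stated, and the libraries cannot be tied to mouse numbers. The recovered factors were 1.00269 and 0.940389 in WT and 1.10132 and 0.969712 in KO, and median-of-ratios factors recomputed from the counts were 1.00268, 0.940378, 1.10132 and 0.969715. The 4 libraries held 22629288 to 24814798 counts over listed genes, and their 20 most abundant genes took 19.6% to 24.9%. Over 12100 genes with a mean of at least 50, Pearson's r of log2 values across genes, which are not independent replicates, was 0.989 within WT, 0.981 within KO and 0.969 to 0.978 between genotypes. The 2 libraries of each genotype differed by more than sampling noise, with chi-square values of 31.3 and 28.2 per degree of freedom, so neither pair was treated as 1 library entered again. Libraries prepared separately from 1 mouse would exceed this noise too, so the values do not show that they came from separate mice. On simulated data 100% of 14617 genes were recovered exactly from means of 2 libraries, and 2.1% of 2000 genes had a solution in 2 steps when the means were made from 3.

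The plan fixed before the data were examined was a test on each sample's counts, or, for a table without values per sample, the authors' adjusted p. The table gave no values per sample, so the authors' FDR under 0.05 is the main result, described as theirs. After the recovery of the counts, a limma fit was added: log2 of the normalized count plus a pseudocount of 1, genes with a mean of at least 10, trend and robust empirical Bayes, KO minus WT, two-sided, with Benjamini-Hochberg adjustment over 14053 genes. Fold changes are then on the log2 scale with that pseudocount, which understates the change of low genes. With 2 against 2 libraries it has 2 residual degrees of freedom, and its p-values measure the spread between these libraries. Tested on data simulated for the same comparison over 14062 genes, with 200 changed, it called 76.8% of genes changed 2-fold and 99% of genes changed 4-fold, and 6.95% of its calls were unchanged genes. All simulated genes shared the same dispersion, which real genes do not, so these rates may not hold for the data.

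34 gene lists were fixed before the data were examined. Each list's members past the FDR were counted over all genes and adjusted over the list alone. Its median log2 ratio was placed among 10000 random lists of the same size, drawn for each member from the 100 genes on either side of it in mean expression. On simulated data 6% of 100 unchanged lists lay outside the middle 95%. The simulated genes varied independently, so this does not give the error rate for lists of correlated genes. Camera with a preset correlation of 0.01 and with an estimated correlation, and fry, were run on the limma fit. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit. Its lowest adjusted p over the lists was 0.473, so such values do not show that a list stayed unchanged. List medians without 1 library are on the same scale as the deposited ratio, as the log2 ratio of mean normalized counts over all listed genes. Leaving out 1 KO library leaves the other against the WT mean, so such values repeat the medians given per KO library. Lists of 29 imprinted genes and 7 genes that escape X inactivation were written after the data were seen.

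The rule for named genes, also fixed before, takes Prmt7, the 10 genes with the smallest adjusted p in each direction without predicted genes, up to 4 passing members of each list or the 2 with the smallest p where none passed, every measured sex-linked gene, and from the pathway tables the 5 smallest p and z scores of 2 or more in size. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen. Gene identifiers were matched by symbol to GENCODE M21 for 13932 genes. The alternatives tried were other thresholds on the deposited p-values, other pseudocounts, filters and scalings of the limma fit, fits without robust moderation and with voom weights, and leaving out each recovered library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.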

Results

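Messenger RNA was measured by sequencing in the tibialis anterior, a fast limb muscle of the lower leg, of mice that lack Prmt7 and of wild-type mice at 8 months. Prmt7 encodes protein arginine methyltransferase 7, an enzyme that methylates arginine residues of proteins. The labels give 3 mice of each genotype. The deposited table holds a mean per genotype for 14617 genes, and each mean could be taken apart exactly into the counts of 2 libraries per genotype, not 3. The 4 recovered libraries held 23695468 and 22629288 counts over the listed genes in WT, and 24814798 and 22849273 in KO. They are called WT library 1 and 2 and KO library 1 and 2, and carry no mouse number. No header states which column of means belongs to which genotype: WT was read as the first and KO as the second from the order of the words in the table's name, and every direction rests on that order.

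The comparison asks which transcripts differ between muscle without Prmt7 and wild-type muscle. The Prmt7 transcript itself (chromosome 8, 106211054 to 106251694 in mm10) had 885 and 844 normalized counts in the WT libraries and 706 and 718 in the KO libraries. The authors' deposited table gives a log2 ratio of -0.28 with an FDR of 0.587, so the transcript lay lower in both KO libraries without passing the threshold of 0.05. The labels do not say which part of the gene is deleted, and reads from exons outside it would not be lowered, so this value neither settles the column order nor checks the knockout.

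The sex-linked transcripts split the libraries. Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460373 to 103483233), had 10800 and 11546 normalized counts in the WT libraries and 2 and 1 counts in the KO libraries (FDR listed as 0 in the authors' deposited table). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 counts in both WT libraries and in KO library 1. In KO library 2 they had 2824, 1378, 715 and 427 normalized counts. A count of 0 allows up to 3 counts in a library. Of 5 measured sex-linked transcripts Xist alone passed the authors' FDR, also when adjusted over the list alone. The labels give no sex, and Xist therefore separates the libraries in the same way as the genotype. Leaving out the genes on the X and Y chromosomes, 377 genes had an FDR under 0.05, against 396 with them. The FDR was kept as deposited, and these 377 genes come from the same libraries, so a difference of sex stays possible for each.

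**Figure D1:**
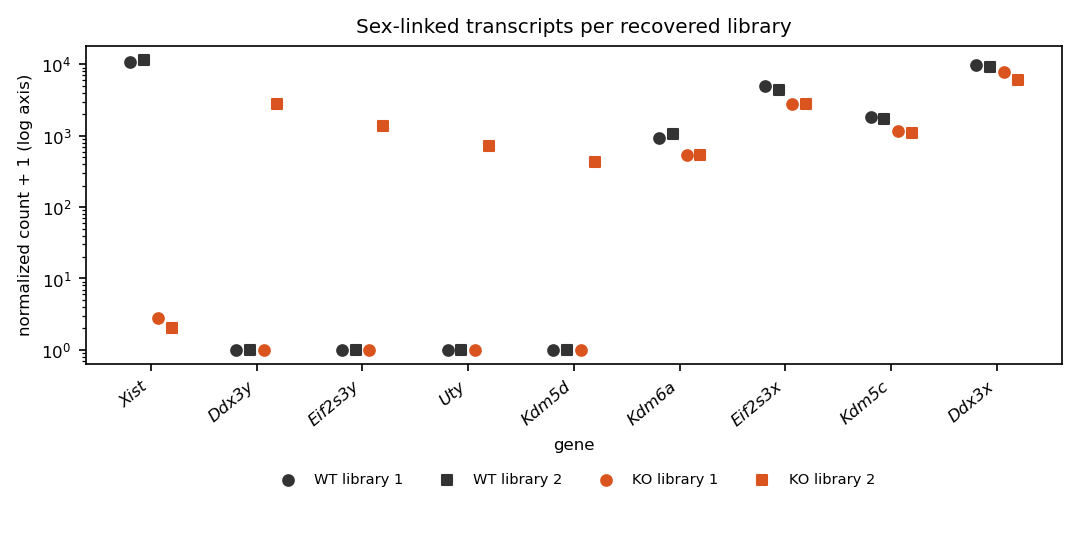
Normalized count plus 1 (log axis) of Xist, 4 Y-linked genes and 4 X-linked genes in each of the 4 recovered libraries; circles and squares are libraries 1 and 2, dark points WT and orange points KO. Xist stood above 10000 in both WT libraries and near 1 in both KO libraries, and the Y-linked genes stood above 0 in KO library 2 alone.

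In the authors' deposited table, 396 of 14617 genes had an FDR under 0.05, 148 higher and 248 lower in KO. With an absolute log2 ratio of at least 1 as well, 40 were higher and 29 lower, so the excess of lower genes did not hold among the larger ratios. The comparison was made with Xist present in both WT libraries and in neither KO library. Myoglobin (Mb), the oxygen store of muscle, fell 3.38-fold, from 141455 and 157768 normalized counts in the WT libraries to 42719 and 45768 in the KO libraries (FDR 7.36e-32 in the authors' deposited table). Ckmt2, the sarcomeric mitochondrial creatine kinase, fell 2.33-fold, from 80910 and 79212 to 34443 and 34292 (FDR 6.28e-15, same table). Alas1, the first enzyme of heme synthesis, fell 2.43-fold, and the mitochondrial carrier family gene Slc25a34 fell 3.2-fold. The fast myosin heavy chain Myh1, the 2X isoform, fell 2.19-fold from 252508 and 246042 to 117179 and 110753. Timp4, an inhibitor of matrix metalloproteinases, fell 2.56-fold, Adck3, needed for coenzyme Q synthesis, 2.26-fold, Asb11 2.18-fold, and Got2, the mitochondrial aspartate aminotransferase, 2.01-fold. For each of these 9 genes both KO libraries lay below both WT libraries.

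Refitted with limma on the recovered counts, a test chosen after the data were seen, 125 genes had an adjusted p under 0.05, 60 higher and 65 lower in KO. Of these, 123 were among the authors' calls, each with the same sign. The limma log2 difference was -1.76 ± 0.18 (SE) for Mb (adjusted p = 0.0192), -1.22 ± 0.164 for Ckmt2 (adjusted p = 0.0376) and -1.67 ± 0.112 for Slc25a34 (adjusted p = 0.00377). Myh1 missed its threshold at an adjusted p of 0.0524. The split depended on the scaling of the libraries, at 156 higher and 50 lower with totals without the top 20 genes, 62 and 38 with total counts, 71 and 51 with the upper quartile and 50 and 42 with quantile normalization. Without robust moderation limma called 27 genes. With WT library 1 left out it called 11 genes, with WT library 2 left out 67, with KO library 1 left out 223 and with KO library 2 left out 381.

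Among the genes higher in KO with the lowest FDR, Dlk1, an imprinted gene for a membrane protein of the Delta family, rose 2.67-fold, from 204 and 244 to 597 and 597 normalized counts (chromosome 12, 109452823 to 109463336; FDR 1.83e-09 in the authors' deposited table). Cish, a cytokine-induced inhibitor of STAT signalling, rose 7.53-fold, from 159.6 and 395 to 1771 and 2401 (FDR 4.95e-08, same table). Its WT libraries differed from each other, and limma gave an adjusted p of 0.124 for it. Kcne1l, a potassium channel subunit, rose 3.16-fold, the corneal and tendon proteoglycan Kera 2.02-fold, the secreted collagen regulator Cthrc1 2.89-fold and the microfibril protein Mfap4 1.78-fold. Tlcd2 rose 2.34-fold, the metalloproteinase Adamts20 2.14-fold, Asb5 1.71-fold, and Gatm, the first enzyme of creatine synthesis, 2.06-fold. Each of these 10 genes except Cish passed limma's adjusted threshold too, with Dlk1 at 0.0142 and Asb5 at 0.046.

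**Figure D2:**
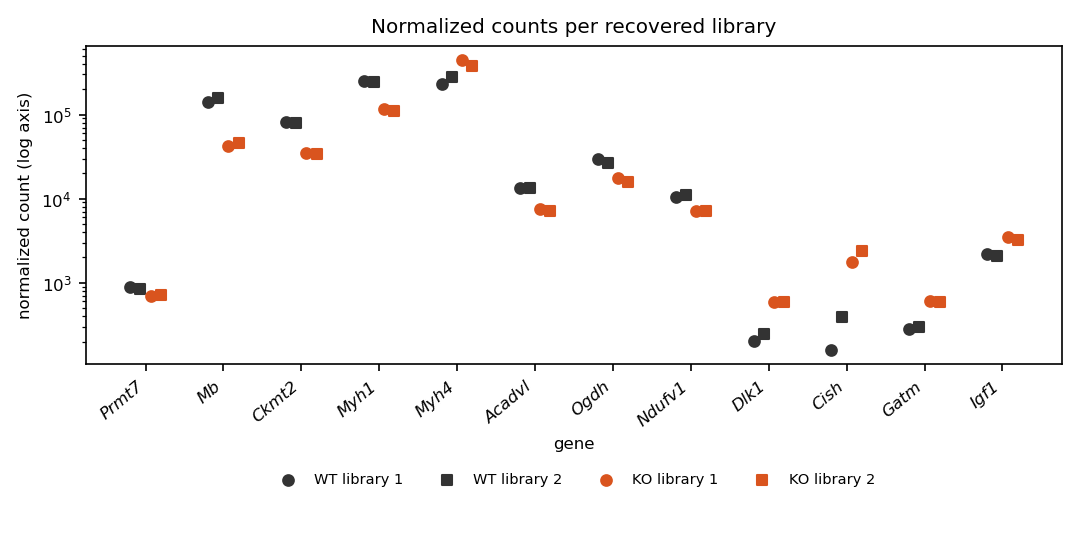
Normalized count (log axis) of 12 named genes in each of the 4 recovered libraries; circles and squares are libraries 1 and 2, dark points WT and orange points KO. The KO points of Mb lay at 42719 and 45768 against 141455 and 157768 in WT, and those of Dlk1 at 597 and 597 against 204 and 244.

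Of 51 measured nuclear-encoded subunits of the respiratory chain, 18 fell, 0 rose and 33 did not pass the authors' FDR (29 fell when adjusted over the list alone). All 51 had a log2 ratio below 0, with a median of -0.41 and camera's adjusted p = 0.573 under an estimated correlation between genes. The median relative to the WT mean was -0.56 in KO library 1 and -0.26 in KO library 2. In the same 2 libraries the medians were 1.48 and -0.29 for adipocyte genes, 1.30 and 0.40 for Schwann cell genes, 0.57 and 0.15 for the extracellular matrix and 0.10 and 0.35 for fast fibre genes, beside -0.51 and -0.46 for the tricarboxylic acid cycle and -0.63 and -0.71 for fatty acid oxidation. Ndufv1 of complex I went from 10563 and 11019 to 7051 and 7054 normalized counts (FDR 0.00184 in the authors' deposited table), Atp5b of ATP synthase from 110092 and 109885 to 74393 and 73551, Uqcrc1 of complex III from 25060 and 26926 to 17306 and 17560, and Ndufa10 of complex I from 8730 and 8928 to 5687 and 6139. Of 15 genes of the tricarboxylic acid cycle, 10 fell and 0 rose (13 fell when adjusted over the list alone), with a median log2 ratio of -0.50 and an adjusted p = 0.473 under an estimated correlation. Ogdh, of the 2-oxoglutarate dehydrogenase complex, fell 1.68-fold, from 29245 and 26468 to 17443 and 15710, Mdh1 1.64-fold and Dlst 1.52-fold. Of 28 genes of fatty acid uptake and oxidation, 16 fell and 0 rose (22 fell when adjusted over the list alone), with a median of -0.67 and an adjusted p = 0.473 under an estimated correlation. Eci1 fell 1.92-fold, Acadvl 1.81-fold, from 13386 and 13367 to 7622 and 7146, Hadha 1.75-fold and Acaa2 1.72-fold.

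The medians of the respiratory chain and fatty acid lists lay below all 10000 random lists matched on mean expression, and that of the cycle at percentile 0.09. The fry test gave an adjusted p of 0.199 for the respiratory chain, 0.0456 for the cycle and 0.0456 for fatty acid oxidation. In the limma fit 0 of the respiratory chain genes, 0 of the cycle genes and 9 of the fatty acid genes passed the adjusted threshold. Both KO libraries lay below both WT libraries for 83 of the 94 genes (88.3%), against 28.3% of autosomal genes with a mean of at least 50 and 16.7% of random orderings of the 4 libraries. The 94 genes share the same 4 libraries and can move together, so these shares describe the genes and are not a test. Of 18 measured regulators of oxidative metabolism, 1 fell and 0 rose (9 fell when adjusted over the list alone). That gene was Perm1, a muscle regulator acting with PGC-1 and ERR factors, from 6628 and 6035 to 4503 and 3811 normalized counts. The list's median of -0.37 lay below all random lists, with camera's adjusted p = 3.95e-04 under the preset and 0.473 under an estimated correlation. The mitochondrially encoded transcripts were not analysed here.

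Of 25 genes of glycolysis and glycogen, 3 fell and 0 rose (8 fell when adjusted over the list alone). They were Ldhb, the heart-type lactate dehydrogenase subunit, at 1.78-fold, Gys1, glycogen synthase, at 1.8-fold, and Pfkm, muscle phosphofructokinase, at 1.6-fold. The list's median was -0.18, at percentile 34.9 of random lists, inside their middle 95%; camera's adjusted p was 6.05e-04 with the preset and 0.473 with an estimated correlation, and fry's adjusted p was 0.0456. Of 18 genes of insulin signalling and glucose uptake only Txnip, an inhibitor of glucose uptake, passed, lower by 1.4-fold (1 rose and 4 fell when adjusted over the list alone), at a list median of -0.16. Of 26 measured lipid synthesis genes, 3 fell and 0 rose (also 3 when adjusted over the list alone): Lpin1 by 1.54-fold, Acacb by 1.72-fold and Dgat2 by 1.69-fold. The median of that list was -0.03, inside the middle 95% of random lists, but -0.263 without KO library 1 and 0.079 without KO library 2, on opposite sides outside it. The insulin list's median was -0.238 without KO library 1, also outside. It was -0.158 without WT library 1, -0.081 without WT library 2 and -0.095 without KO library 2, each inside.

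The contractile genes moved in both directions. Of 16 fast fibre genes, 2 rose and 1 fell (4 and 2 when adjusted over the list alone), with a median log2 ratio of 0.24. Myh4, the 2B myosin heavy chain, rose 1.6-fold, from 232372 and 277492 to 444884 and 373640 normalized counts (FDR 0.0113 in the authors' deposited table), and Mybpc2, the fast myosin-binding protein C, rose 1.5-fold. Neither passed in limma (adjusted p = 0.172 and 0.178). Myh1 was the gene that fell. Of 15 slow fibre genes, 3 fell and 0 rose (3 fell and 1 rose when adjusted over the list alone): Mb, the ventricular and slow light chain Myl3, by 2.02-fold, and Casq2, a calcium store protein, by 1.57-fold. The median of this list was 0.21, above 0, while its called members were below it. With an estimated correlation camera gave adjusted p = 0.867 for the fast and 0.856 for the slow list. Without KO library 1 the slow list's median was 0.02, inside the middle 95% of random lists, and it was 0.392 without WT library 1, 0.229 without WT library 2 and 0.327 without KO library 2. The fast list's median was 0.103 without WT library 1, 0.098 without KO library 2, 0.354 without KO library 1 and 0.425 without WT library 2.

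**Figure D3:**
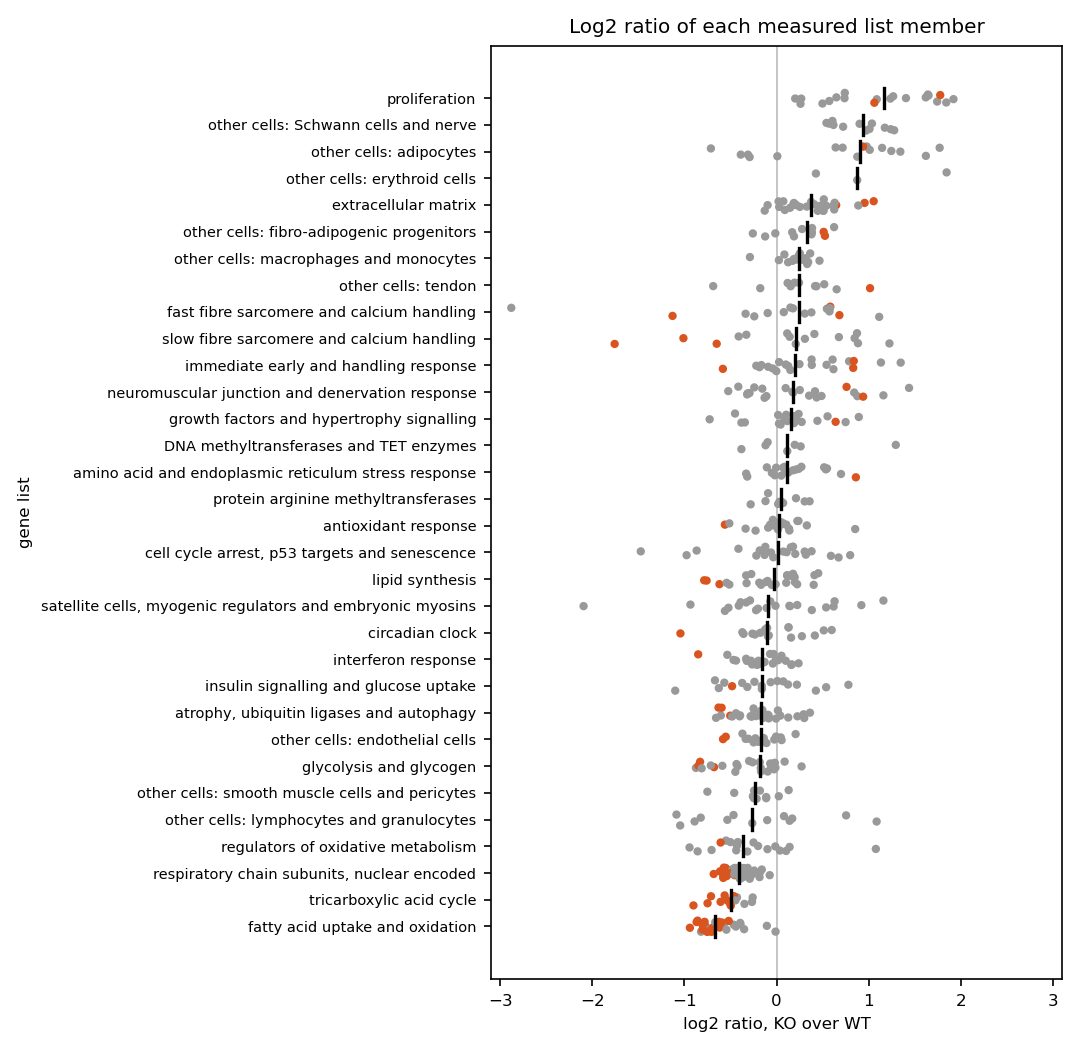
Log2 ratio of KO over WT of each measured member (points) of the fixed gene lists, with orange points at an FDR under 0.05 in the authors' deposited table and grey points above it; black bars are list medians. The 3 lists of oxidative metabolism lay at the lower end, with medians of -0.67, -0.50 and -0.41.

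Of 20 proliferation genes, 2 rose and 0 fell (5 rose when adjusted over the list alone). E2f1, a transcription factor of the cell cycle, rose 2.09-fold, from 103 and 74.4 to 161 and 209 normalized counts, and the mitotic checkpoint kinase Bub1 rose 3.43-fold, from 32.9 and 13.8 to 65.4 and 94.9. All 20 members had log2 ratios above 0, with a median of 1.16. The median relative to the WT mean was 0.73 in KO library 1 and 1.48 in KO library 2. The list's median was above all random lists, with camera's adjusted p = 0.573 under an estimated correlation. Of 29 extracellular matrix genes, 3 rose and 0 fell (5 rose when adjusted over the list alone). Collagen Col3a1 rose 1.94-fold, periostin (Postn) 2.08-fold and Col1a2 1.57-fold. The median of 0.38 lay above all random lists, with an adjusted p = 0.69 under an estimated correlation. Relative to the WT mean it was 0.57 in KO library 1 and 0.15 in KO library 2, beside 0.45 and 0.12 for markers of fibro-adipogenic progenitors and 0.44 and 0.09 for tendon markers. The matrix median was 0.149 without KO library 1 and 0.576 without KO library 2, which restates the values per KO library.

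Of 22 genes of growth signalling 1 rose, Igf1, insulin-like growth factor 1, from 2209 and 2104 to 3482 and 3247 normalized counts, and 0 fell (the same count when adjusted over the list alone). Of 23 genes of the neuromuscular junction, 2 rose and 0 fell (4 and 2 when adjusted over the list alone): Colq, the collagen tail of acetylcholinesterase, by 1.92-fold and Chrne, the adult acetylcholine receptor subunit, by 1.69-fold. Of 29 genes of atrophy and autophagy, 3 fell and 0 rose (7 fell when adjusted over the list alone): Map1lc3a by 1.51-fold, Fbxo31 by 1.42-fold and Ddit4 by 1.55-fold. Of 22 immediate early genes, Fos rose 1.78-fold, Myc 1.79-fold and Cyr61 fell 1.5-fold, with the same 2 and 1 when adjusted over the list alone. Camera's adjusted p with an estimated correlation was 0.69 for growth signalling, 0.51 for the junction, 0.473 for atrophy and 0.473 for the immediate early genes, whose list medians of 0.15, 0.18, -0.17 and 0.20 lay outside the middle 95% of random lists. Leaving out 1 library put each of these 4 medians inside. Growth signalling was at 0.028 without WT library 1, 0.097 without KO library 1 and 0.12 without KO library 2, and at 0.283 and outside without WT library 2. In limma with all 4 libraries it was 0.125, also inside. The junction list was at 0.105 without KO library 2 and the atrophy list at -0.122 without WT library 2. The immediate early list was at 0.183 without WT library 1, 0.132 without WT library 2 and 0.177 without KO library 1. Of 19 genes of the circadian clock, 1 fell and 0 rose (1 fell and 1 rose when adjusted over the list alone), with a list median of -0.10. That median was -0.050 without WT library 1, -0.001 without WT library 2 and 0.041 without KO library 1.

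Of 20 measured stress response genes Psat1, of serine synthesis, rose 1.82-fold and none fell (4 rose when adjusted over the list alone). Of 20 antioxidant genes Sod2, the mitochondrial superoxide dismutase, fell 1.48-fold, and of 24 interferon response genes Ifi44 fell 1.8-fold, with the same single gene in each when adjusted over the list alone. The interferon list's median of -0.16 was at percentile 0.34 of random lists, but inside their middle 95% without WT library 1 (-0.097), KO library 1 (-0.104) or KO library 2 (-0.112), and camera's adjusted p with an estimated correlation was 0.51 for it and 0.473 for the stress list. Besides 5 lists of markers of other cells, no member passed in 4 lists. They were 22 measured satellite cell and myogenic genes, 22 p53 and senescence genes, 10 protein arginine methyltransferases and 7 DNA methyltransferases and TET enzymes, and none did when adjusted over the list alone. At an unadjusted p under 0.05 in the authors' deposited table, 1 satellite cell gene was higher and 1 lower, 2 p53 genes were higher and 3 lower, 1 DNA methylation gene was higher and 1 lower, and no methyltransferase of arginine differed; limma called none in any of these 4. Leaving out 1 library put list medians that lay inside the middle 95% of random lists outside it, at 0.208 for stress without WT library 1 and 0.134 without KO library 2, 0.086 for antioxidants, -0.175 for satellite cells and -0.167 for the circadian clock without KO library 2, and 0.268 for DNA methylation without WT library 1. Other libraries left out gave the opposite sign, inside that range. The medians were then 0.075 for satellite cells and 0.041 for the circadian clock without KO library 1, and -0.019 for DNA methylation without WT library 2. Besides Prmt7, the members with the smallest p in the 4 lists without a passing member named above were Mef2d (3295 and 3156 in WT, 2569 and 2286 in KO) and Myod1 (466 and 422, 558 and 732), Sesn1 (1338 and 1473, 1127 and 984) and Phlda3 (6827 and 4827, 3791 and 2597), Prmt10 (229 and 254, 307 and 291), and Dnmt3a (4052 and 3719, 3101 and 2865) and Uhrf1 (89.8 and 50, 125 and 218), in normalized counts.

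Markers of other cells differed between the 2 KO libraries. The median log2 ratio of 16 adipocyte genes to the WT mean was 1.48 in KO library 1 and -0.29 in KO library 2, and that of 12 Schwann cell genes was 1.30 and 0.40. Mest was the only adipocyte list member to pass, higher by 1.92-fold, and no Schwann cell gene passed, with Mag at 52.9 and 46.8 in WT and 142 and 93.8 in KO and Cnp at 573 and 488 and 881 and 665. Of 12 markers of fibro-adipogenic progenitors, the connective tissue cells of muscle, Dpt rose 1.43-fold and Clec3b 1.44-fold. Of 11 tendon genes Kera rose, and of 16 endothelial genes Kdr fell 1.47-fold and Flt1 1.5-fold, both receptors of vascular growth factor. None of 17 macrophage, 13 lymphocyte and granulocyte, 12 smooth muscle and 3 erythroid genes passed. Adjusted over the list alone, 4 progenitor, 2 tendon, 1 Schwann cell and 1 adipocyte genes rose, and 2 endothelial, 1 smooth muscle and 1 tendon genes fell. The smallest p among the macrophage, lymphocyte and granulocyte, smooth muscle and erythroid genes belonged to C1qb (1314 and 875 in WT, 1624 and 1401 in KO), S100a9 (18 and 55.3, 84.4 and 71.2), Myh11 (2327 and 2392, 1772 and 1659) and Slc4a1 (4.99 and 12.8, 46.3 and 17.5). The list medians were 0.25, -0.26, -0.23 and 0.88, and at an unadjusted p under 0.05 in the authors' deposited table only 1 lymphocyte or granulocyte gene was higher and 1 lower, and 1 smooth muscle gene lower. In the limma fit, whose filter removes Cd3g, Cd8a and Nkg7 with negative ratios, the lymphocyte median was 0.040 and camera's direction up, against the negative median of all members, and the adipocyte median was 0.528. Without WT library 2 the macrophage median was -0.024 and without WT library 1 it was 0.545. Without KO library 1 the medians were 0.059 for macrophages, -0.294 for adipocytes, 0.398 for Schwann cells, 0.119 for progenitors and 0.092 for tendon, and without KO library 2 they were 0.34, 1.5, 1.31, 0.453 and 0.441. The macrophage values without WT library 2 or KO library 1, and the progenitor and tendon values without KO library 1, lay inside the middle 95% of random lists. The erythroid median was 1.23 without KO library 2, outside it, and 0.411 without KO library 1. The lymphocyte median lay inside it without WT library 1 (-0.115) or KO library 2 (-0.196), and the smooth muscle median with any 1 library left out, between -0.233 and -0.141. Camera's adjusted p with an estimated correlation was 0.856 for adipocytes, 0.573 for Schwann cells, 0.69 for progenitors, 0.69 for tendon, 0.473 for endothelial cells, 0.736 for macrophages, 0.473 for smooth muscle and 0.97 for lymphocytes.

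The authors' pathway tables were made from genes with an absolute log2 ratio of at least 0.95 and their header names no limit on p. Among the listed genes 738 passed that limit, 547 higher and 191 lower in KO, and 499 of them had a mean under 50 normalized counts, 377 higher and 122 lower. Of the 738 genes, 79 had an FDR under 0.05, while 317 genes with an FDR under 0.05 did not reach the limit. The authors' deposited table of pathways, with 202 entries, was led by Mitotic Roles of Polo-Like Kinase, where 12 of 12 molecules were higher in KO and 0 had an FDR under 0.05, and by the G2/M DNA damage checkpoint with 10 molecules. Catecholamine biosynthesis, 14-3-3 sigma signalling and CHK checkpoint control came next, with 3, 5 and 8 molecules. The authors' deposited table of 608 upstream regulators lists PTGER2, CSF2 and CCND1 with the smallest p and activation z scores of 4.793, 6.466 and 3.494, FOXM1 at 3.916 and EP400 at 3.719. It lists NUPR1 at -4.938, KDM5B at -3.761, BNIP3L at -3.637, CDKN1A at -3.44 and Irgm1 at -3.357. TGFB1, at -0.807, and E2F4, with no z score, completed the 5 with the smallest p. The authors' bias-corrected z scores were 2.453 for PTGER2, 3.523 for CSF2, 1.952 for CCND1, 2.189 for FOXM1 and 2.057 for EP400. They were -3.953 for NUPR1, -2.849 for KDM5B, -3.097 for BNIP3L, -2.797 for CDKN1A and -1.778 for TGFB1, with none given for Irgm1. With that correction CCND1 lay under 2. Pathway z scores of at least 2 were listed for cyclins and cell cycle regulation (2.828), estrogen-mediated S-phase entry (2.236), aryl hydrocarbon receptor signalling (2.236), colorectal cancer metastasis signalling (2.121) and Gαi signalling (2), and of -2 for the G1/S checkpoint and JAK/Stat signalling. The authors' negative log10 of the pathway p was 2.71 for cyclins and 3.25 for S-phase entry. For the rest it was, in the order above, 1.27, 0.414, 0.331, 0.932 and 0.798, each a p above 0.05. The Gαi, G1/S and JAK/Stat entries held 4 molecules each. None of the 94 genes of the 3 oxidative lists reached the limit of 0.95, though 44 had an FDR under 0.05, while 12 of 20 proliferation genes reached it and 2 had such an FDR.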

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

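All tests in this part except that of the scaling were chosen after the result was seen. KO library 2 held 5181 counts of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together, while both WT libraries held 0, a signal above the level in the control libraries.

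KO library 1 held neither Xist (2 counts) nor Y-linked transcripts. Its 4 Y-linked genes summed to 0 counts, at most the 3 counts that a count of 0 allows, which argues against a male mouse as its source. The 7 genes listed as escaping X inactivation had a median log2 ratio to the WT mean of -0.558 in KO library 1 and -0.650 in KO library 2, and all 7 lay below both WT libraries in both. A candidate explanation is a single X chromosome in the mouse behind KO library 1, which these values fit but which the labels do not address. The median over 400 X-linked genes with a mean of at least 50 was 0.044 in that library. Kdm6a (927 and 1044 in WT, 543 and 537 in KO), Eif2s3x (4937 and 4401, 2816 and 2781) and Kdm5c (1836 and 1722, 1154 and 1085) had an FDR under 0.05 in the authors' deposited table.

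The 94 genes of the respiratory chain, the tricarboxylic acid cycle and fatty acid oxidation had a median log2 ratio of -0.466, which under 5 other scalings of the libraries stayed between -0.479 and -0.320 and so argues against scaling as the whole cause. RNA from other cells would lower all muscle fibre transcripts alike, yet the fast fibre list had a median of 0.243 (0.098 to 0.425 leaving out 1 library), apart from the 94 genes at a permutation p of 1e-05, the smallest that 100000 permutations can give; genes are not independent, and this argues against other cells as the whole cause only. Relative to the WT mean the fast list was at 0.098 in KO library 1 and 0.354 in KO library 2, and the 94 genes at -0.572 and -0.423, so a contribution of other cells to the lower values in KO library 1 stays open. The presence of Xist cannot be told apart from the genotype here, since 0 WT libraries lacked it. Y-linked transcripts were found in KO library 2 alone, while the 94 genes were lower in both KO libraries. That contrast sets 1 library against 1, so the sex of the mice stays open as a cause. The loss of Prmt7 stays among the open explanations and may act through fibre composition or otherwise, which was not tested.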

How the results depend on the processing

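The limma fit of the recovered counts, its settings and all leave-one-out values were added after the data were seen. The count of 396 genes became 1629 at an unadjusted p under 0.05, 206 at an FDR under 0.01, 69 with an absolute log2 fold change of at least 1, and 125 in limma; 533 at an FDR under 0.10 and 401 when adjusted over genes with a mean of at least 10 stayed within 1.5 times. Limma's 125 became 206 (156 higher, 50 lower) when libraries were scaled without the top 20 genes, which moved the median of all genes to 0.11, 100 (62 higher, 38 lower) with total counts and 122 (71 higher, 51 lower) with the upper quartile. It was 27 without robust moderation. Leaving out 1 library gave 11 to 381, the lone library of a genotype being assumed to vary like the others. Prmt7 stayed below 0 and short of the threshold in every setting run. Of all list members 83 passed the FDR, 208 an unadjusted p and 46 an FDR under 0.01. In limma 22 passed, and with other settings 22 (pseudocount 0.1), 19 (pseudocount 10), 24 (no filter), 17 (totals), 18 (upper quartile), 21 (without the top genes), 13 (quantile), 19 (median centring), 19 (mean of at least 50), 5 (no robust moderation) and 14 (voom weights), or 1 to 71 without 1 library. For 20 of 32 lists the median lay outside the middle 95% of random lists; camera called 17 with the preset and 0 with an estimated correlation, fry 3, and leaving out 1 library gave 14 to 21 on the deposited scale and 13 to 20 in limma. Calls shared by limma and the authors numbered 123, or 1593 at an unadjusted p in both, 27 without robust moderation and 10 to 196 without 1 library. Leaving out 1 library, the adipocyte median lay between -0.294 (without KO library 1) and 1.5 on the deposited scale and from -0.268 in limma, and the macrophage median between -0.024 (without WT library 2) and 0.545, or -0.031 and 0.542 in limma. The lymphocyte median of -0.26 stayed negative on the deposited scale with any library left out, between -0.377 and -0.115. In limma without a filter it was also negative, and the filter removes Cd3g, Cd8a and Nkg7, which have negative ratios and a mean under 10. With the filter it was 0.040, or 0.041 and 0.037 with pseudocounts of 0.1 and 10, 0.088 with totals, 0.080 with the upper quartile, 0.147 without the top genes, 0.030 with median centring, 0.188 with a mean of at least 50, 0.040 without robust moderation, 0.043 with voom weights, negative with quantile normalization and, leaving out 1 library, between -0.148 and 0.107. Of 84 named genes with a finite ratio, besides Prmt7, none changed sign in the settings run, of which the filter at a mean of at least 50 kept 82, and 35 that had passed did not in limma. The genes were named mostly for a small p in these same libraries, which every setting reuses, so the unchanged signs are no independent check. Other causes were not tested. Of the settings chosen before, negative binomial count models with their own normalization and filter were not run. The series of mouse numbers as a covariate, 4 of the mice alone and each of the 6 mice left out were not run either, since the recovered libraries carry no mouse number. No paired analysis was possible because the libraries cannot be tied to mouse numbers. Depth limits genes with few counts.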

Other observations

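The lists and tests in this part were chosen after the values were seen. Of 24 measured imprinted genes, 9 were higher and 1 was lower in KO at an FDR under 0.05 in the authors' deposited table, with a median log2 ratio of 0.695, and 17 (70.8%) lay above both WT libraries in both KO libraries, against 24.4% of autosomal genes and 16.7% of random orderings. Since the genes share the same libraries, these shares are a description and not a test. Besides Dlk1, its neighbours on chromosome 12 Meg3 (2536 and 3040 normalized counts in WT, 5929 and 4670 in KO), Rian (3570 and 3854, 6521 and 5917) and Mirg (88.8 and 141, 263 and 261) rose, as did Plagl1, Ndn, Peg3, Peg10 and Mest, while H19 fell from 114737 and 115315 to 68421 and 90354.

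A candidate explanation is a larger share of fibro-adipogenic progenitors, whose list had a median of 0.329 (0.119 without KO library 1 and 0.453 without KO library 2), with quartiles of 0.124 and 0.417 that overlap those of the imprinted genes (0.316 and 0.927). Another is regenerating fibres: the list of satellite cell genes and embryonic myosins had a median of -0.087 and quartiles of -0.375 and 0.344. That median was 0.075 without KO library 1 and -0.175 without KO library 2, so its sign depended on 1 library. Members went in both directions, among them Myog at a log2 ratio of 1.16, Tmem8c at 0.92, Pax7 at -0.52 and Myh8 at -2.10 in the authors' deposited table, none past the FDR. Neither can be told apart from an effect of the genotype here, since the spreads overlap and the imprinted genes were listed because several had been seen to rise. The rule for this comparison was revised 2 times after the values were seen, and under both earlier rules, a permutation of the lists and an upper quartile (0.417 and 0.344) below the imprinted median of 0.695, the values argued against both explanations, so the verdict changed with the rule. Relative to the WT mean the imprinted genes had medians of 0.518 in KO library 1 and 0.606 in KO library 2. The progenitor list was at 0.451 and 0.118 there, and the satellite cell list at -0.174 and 0.075. The imprinted median was thus not smaller in KO library 2, where the progenitor median was, a contrast that rests on 1 library. The sex of the mice stays open too.

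The following genes were chosen after their values were seen and form no tested group. Socs1 went from 66.8 and 65.9 to 159.8 and 123 normalized counts and Odc1 from 1974 and 1757 to 3064 and 3380, both past the FDR in the authors' deposited table. Socs2 and Socs3 did not pass (FDR 0.296 and 0.403 in the authors' deposited table). Il15 fell 2.11-fold and the transferrin receptor Tfrc 2.11-fold, from 24881 and 27994 to 11104 and 13926. Nnt, the mitochondrial transhydrogenase, fell 2.19-fold, and cardiac actin Actc1 rose 3.74-fold, from 15579 and 25767 to 64303 and 90420.

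For some genes the size of the ratio depended on WT library 1, although both KO libraries also lay below WT library 2. Myh2, the 2A myosin heavy chain, had 109972 normalized counts in WT library 1, 31555 in WT library 2 and 11272 and 7952 in KO, with an FDR of 0.522 in the authors' deposited table. Csrp3 had 20115 and 1922 in WT and 945 and 538 in KO, Ankrd2 9483 and 1929 and 1051 and 706, and Fhl1 166439 and 59536 and 29465 and 20418. WT library 2 stood above WT library 1 for the bone-related genes Ibsp (144 against 0), Mmp13 (360.5 against 46.9) and Acp5 (437 against 106). Pax7, a satellite cell transcription factor, had 52.7 in KO library 1 and 212 in KO library 2, against 178 and 203 in WT.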
